A study of Homo sapiens with 24 samples.

How the data were processed

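Total RNA of H1 cells was measured on Illumina HumanHT-12 v4 bead arrays, per the labels. Each of 6 times after the start of dorsomorphin treatment, from 0 to 72 h, had 4 arrays numbered as replicates 1 to 4. Per the labels' protocols, cells were grown on Matrigel in a stem cell medium, plated as single cells at high density, and moved at confluency to a serum-replacement medium for the treatment, with medium changed daily. RNA was isolated with TRIzol, digested with DNase and purified on columns. Whether the 4 replicates were separate cultures, and how the arrays were spread over slides and days, are not given in the sources used here.

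The deposited values held 37900 rows with log2 values between 5.57 and 15.51, a column for each array. The authors had brought the log2 values of the 24 columns to nearly the same quantiles, as the deposited values themselves show. The scanner software, the background correction, the normalization method and any probe filter behind them are not given in the sources used here. Identical values in all 24 columns were shared by 10159 rows in 4746 sets. In each of the 4037 named sets the rows had the same gene symbol and the same transcript accession, and the other 709 sets had no name. The deposited table therefore repeats a single value over several probes, and which probe it came from is not known. Each set was counted once, which left 32487 measurements. A second deposited table of scanner intensity with a detection p-value per probe was not used, because its 24 intensity and 24 p-value columns carry names that match no sample label. The design planned a background correction with the detection p-values and a filter on them. The deposited log2 values were used in their place with the planned model, a fit first listed only as a variation.

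Gene names came from the platform annotation given with the series, which listed 26228 of the rows, 26221 with 1 symbol and 7 with several. The other 11672 rows were not listed and remained unnamed. Entrez identifiers of 26191 rows were found in the RefSeq gene table, and 0 symbols needed an update. Background was set at 7.10 on the log2 scale, the 99th percentile of 387 olfactory receptor measurements, a gene family taken here as silent in these cells (median 6.41). This background and the treatment of repeated values were chosen after the values were seen, since the detection p-values could not be used. A gene was tested when its measurement lay above background on at least 4 arrays. Where a gene had several measurements, the one with the highest mean over the 24 arrays was taken. Of 17760 named genes, 10217 were tested and 7543 were too dim. Among those tested, 1937 had a value repeated over several probes. Where all 4 arrays of a time lay below background, the change was computed against the background and given as "at least" a fold. Where only some arrays of a time lay above background, the measured difference is given with their number.

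A one-way model with a mean for each time was fitted to all 24 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, which leaves 18 residual degrees of freedom per gene. Each later time was compared with 0 h and each time after 12 h with the one before it, 9 comparisons in all. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. Counts with a change of at least 2-fold are given beside the others. The moderated F test covered the 5 comparisons with 0 h. Standard errors are those of the moderated fit, and standard deviations are those of the 4 arrays. A gene was transient when it passed at least 2-fold at 12, 24, 36 or 48 h and had moved back by at least 2-fold past the threshold by 72 h. The first time of change is the earliest time from which a gene passed both limits at that and every later time. Genes shared by the 12 h and 72 h comparisons were set beside the number for independent lists, simulated unchanged groups and a split of the 0 h arrays.

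There were 28 gene lists with 591 genes, and those with at least 5 tested members went into camera of limma with a preset correlation of 0.01 and, beside it, with a correlation estimated from the residuals. Adjustment ran over all lists and times together. Members were counted as past the gene test over all genes tested and adjusted over the list alone. The comparisons, tests, thresholds, gene lists, rule for naming genes and most variations were chosen before the data were examined.

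Genes were named by a rule. For 72 h against 0 h these are the 10 largest rises and 10 largest falls among genes past the threshold whose 4 arrays at 1 time all lie above the 4 at the other. The other times against 0 h give 5 and 5 by the same criterion, and each interval gives 3 and 3. The rule adds the 4 largest peaks and 4 largest troughs, and up to 4 members past the threshold with the largest change in each list described. It always adds POU5F1, NANOG, SOX2, PAX6, SOX1, OTX2, ID1, ID3, LEFTY1, LEFTY2, TBXT, SOX17, DNMT3A, DNMT3B, TET1, CDH1 and CDH2. Unnamed measurements are passed over, and genes outside the rule are marked as chosen after their values were seen.

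The procedure was tested on simulated data with 20 simulations of the 72 h against 0 h comparison over 10217 genes, in which the residuals of whole arrays were shuffled and 200 genes were changed. Of the changed genes, 78.9% were recovered at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold. The share of false calls had a median of 0.526% and a maximum of 62.6%. Of 50 peaks planted at 4-fold, 99.7% were recovered, with a mean of 0.6 false peaks. In simulated data without changes, camera with the preset correlation called a mean of 23.0 of 135 list tests, at most 45, and at least 1 in 20 of 20 simulations. With the estimated correlation it called 0 of these, so the report gives both.

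Alternatives covered the scaling of the arrays, the filter on dim genes, the choice of measurement per gene, blocks, the variance model, array weights, subsets of arrays, fold limits and the list test. All 35 splits of the 8 arrays of each comparison, or 100 regroupings of the 24 arrays, were refitted to see how often they give as many calls. For the alternation of genes between times, residuals of whole arrays were shuffled 99 times around group means from which that contrast was removed. Correlations across arrays and differences of single values were tested by permutation. Other tools were version 1.17.8 of data.table, and for the plots Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. The number of arrays limits the precision, with 36 pairs of arrays of the same time differing by a median standard deviation of 0.26 on the log2 scale across measurements.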

Results

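H1 is an established human embryonic stem cell line. Dorsomorphin, also called compound C, is a small molecule that inhibits the type I BMP receptors as well as AMPK. The study asked how transcript levels move while confluent H1 cells are turned towards a neural stem cell fate over 72 h. Total RNA was taken at 0, 12, 24, 36, 48 and 72 h, and 4 arrays were hybridised for each time, 24 in all. The values were log2 signals of an Illumina bead array, between 5.57 and 15.51. Of 17760 named genes, 10217 lay above background on at least 4 arrays and were tested, and 9147 to 9412 genes lay above background on any one array. Pairs of arrays of the same time correlated at a median r of 0.987 and at most 0.992 across measurements. The labels do not state that the 4 replicates of a time were separate cultures, so p-values measure only the spread between these arrays, which may be technical. The cells were moved from a stem cell medium to a serum-replacement medium at the start, and no untreated cells were sampled at the later times, so a difference from 0 h holds time in culture, the new medium and the compound together. Array values carry no counts, and the number of arrays limits the precision.

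The total number of genes that differed from 0 h was larger at each later time. At 12 h, 282 genes were higher and 339 lower; at 24 h, 406 and 331; at 36 h, 813 and 925; at 48 h, 1096 and 1072; and at 72 h, 1890 and 1775. Within replicates 1 and 2 the totals did not climb at each step, with 173 at 12 h and 105 at 24 h, and 824 at 36 h and 678 at 48 h, and without replicate 3 at 0 h the higher genes numbered 450 at 12 h and 259 at 24 h. A change of at least 2-fold was reached by 32 and 19 genes at 12 h and by 201 and 218 genes at 72 h. Across the whole course 4994 genes, 48.9% of those tested, varied with time in limma's moderated F test.

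**Figure D1:**
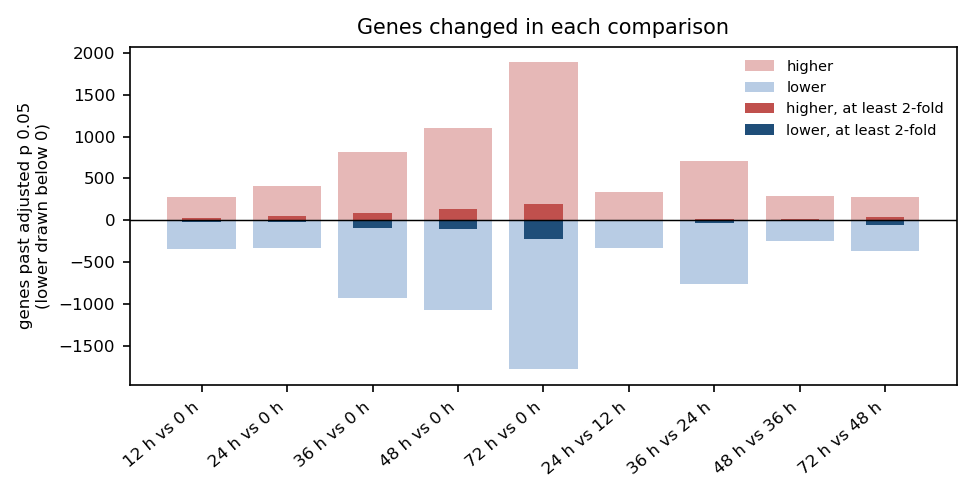
Number of genes past the threshold (vertical axis, higher drawn above 0 and lower below) in each of 9 comparisons of times in hours (horizontal axis), with the narrow dark bars for changes of at least 2-fold. The bars reach 1890 higher and 1775 lower genes at 72 h against 0 h, from 282 and 339 at 12 h.

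The comparison of 72 h with 0 h covers the full induction. Transcription factors of the early neural plate and forebrain stood among the largest rises. SOX21, a SoxB factor of neural progenitors, rose by 3.82 ± 0.21 on the log2 scale (SE; 14.1-fold; adjusted p = 1.4e-12), from 9.36 ± 0.63 (SD) at 0 h to 13.19 ± 0.10 at 72 h. Here and throughout, each time had n = 4 arrays. FEZF1, a forebrain repressor, rose by 3.67 ± 0.36 (adjusted p = 1.3e-08). PAX6, an eye-field and neuroectoderm factor, rose by 3.12 ± 0.27 (adjusted p = 1.6e-09). FEZF1 and PAX6 were each above background on 1 of the 4 arrays at 0 h and on all 4 at 72 h. OTX2, which patterns forebrain and midbrain, rose by 2.23 ± 0.30, SOX2, shared by stem cells and neural progenitors, by 1.13 ± 0.17, and CDH2, the N-cadherin of neural epithelium, by 1.63 ± 0.20. Over the same time NANOG, a core pluripotency factor, became at least 3.63-fold lower and lay below background on all 4 arrays at 72 h. POU5F1 fell by 1.81 ± 0.11 (3.50-fold; adjusted p = 1.1e-11), or stood at -1.12 with the mean of its probes, and remained bright at 10.55 ± 0.29.

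Among the other large rises at 72 h, LMO1, a LIM-domain cofactor, was dim on all 4 arrays at 0 h and at least 16.8-fold higher at 72 h. FRZB, a secreted Wnt antagonist, rose by 3.97 ± 0.32, VWF, the von Willebrand factor, by 4.04 ± 0.32 from a level above background on 1 array at 0 h, and TNFRSF19 by 3.81 ± 0.30. Further rises were those of the ephrin receptor EPHA4 at 3.74 ± 0.28, SHISA2 at 3.51 ± 0.32, the secreted kinase PKDCC at 3.48 ± 0.32 and FST, the activin-binding follistatin, at 3.39 ± 0.42. Large falls included that of ADM, the peptide adrenomedullin, at -3.83 ± 0.46 (adjusted p = 4.9e-07). SPRY4, a feedback inhibitor of ERK signalling, became at least 9.94-fold lower. ETV5, an ETS factor downstream of FGF, went from 9.68 to below background on all 4 arrays. DUSP6, an ERK phosphatase, fell by 3.41 ± 0.26 to a level above background on 1 array. The neuropeptide gene NTS fell by 3.67 ± 0.27, RAB17 by 3.08 ± 0.37, and CFAP95 by 3.02 ± 0.35. The metallothionein MT1X fell by 2.94 ± 0.70, TRIML2 by 2.93 ± 0.19 and the phospholipase PLA2G3 by 2.81 ± 0.14. At 72 h background was exceeded on 2 arrays for NTS and PLA2G3, 1 for TRIML2 and 3 for CFAP95 and MT1X.

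**Figure D2:**
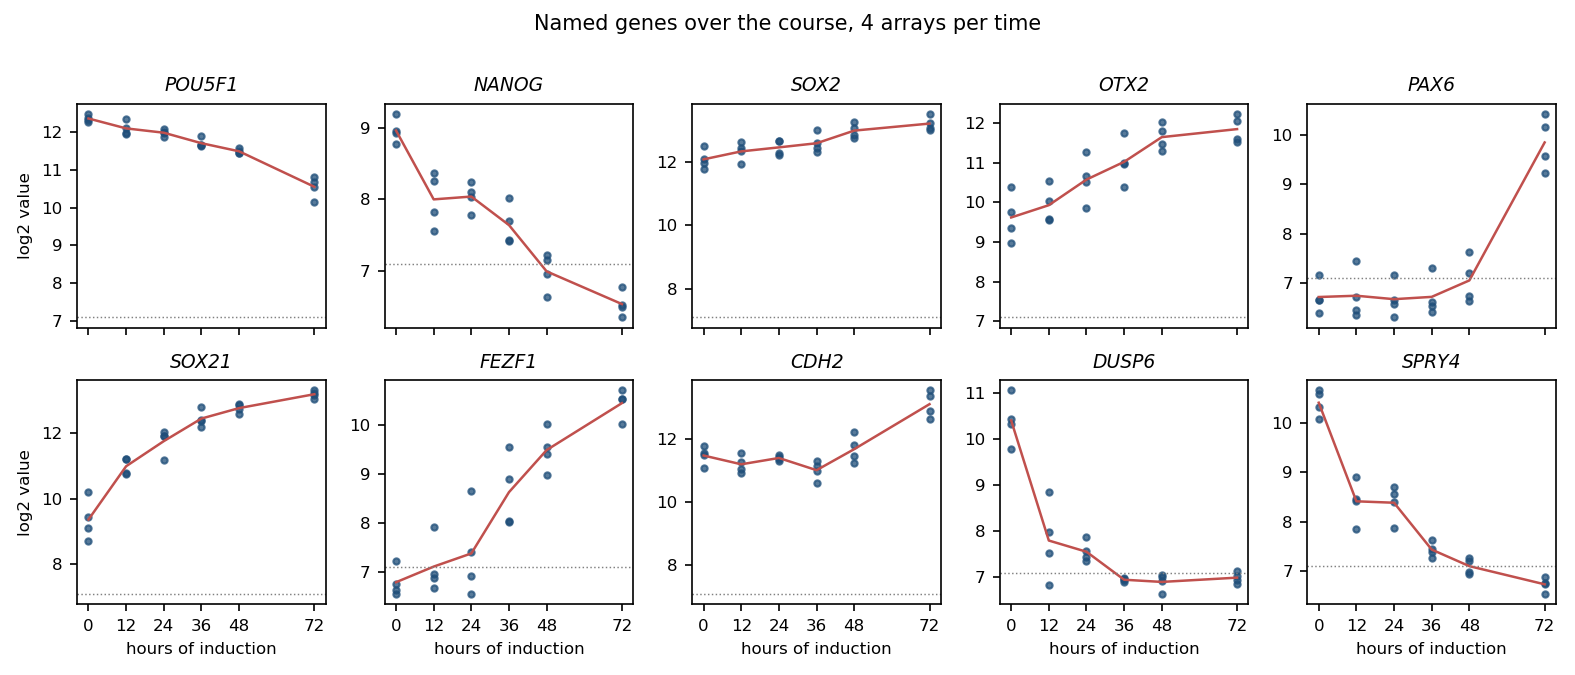
Log2 signal (vertical axis) of 10 genes against time in hours (horizontal axis), with 1 point per array, a red line through the means of 4 arrays and a dotted line at the background of 7.10. SOX21 is higher than at 0 h from 12 h on and OTX2 from 36 h on, PAX6 stays near background until 48 h and reaches 9.85 at 72 h, and DUSP6 and SPRY4 are already low at 12 h.

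Gene lists fixed beforehand moved at 72 h as follows. Of 21 tested pluripotency genes, 13 fell, 4 rose and 4 did not pass. The list was lower (camera adjusted p = 6.3e-06, and adjusted p = 0.0441 with an estimated correlation). Adjusted over the list alone, 14 were lower and 4 higher. With groups below background held at the background, the list's median went from -0.87 to -0.44 and its mean from -0.80 to -0.63. POLR3G, a polymerase III subunit of stem cells, fell by 2.43 ± 0.17, L1TD1, an RNA-binding protein of stem cells, by 2.05 ± 0.24, and ETV4 became at least 5.75-fold lower. Of 35 neural plate and neural stem cell genes, 23 rose, 1 fell and 11 did not pass, and adjusted over the list alone 24 were higher and 1 lower (camera adjusted p = 3e-12; adjusted p = 0.107 with an estimated correlation). HESX1, an anterior neural factor, rose by 3.39 ± 0.32 and DLK1, a Notch-ligand relative, by 3.19 ± 0.36 from a level above background on 1 array. Of 10 forebrain genes, 8 rose and 1 fell, or 9 and 1 adjusted over the list alone, SIX3 being at least 5.05-fold higher. The list was higher at adjusted p = 1.3e-06, and at adjusted p = 0.107 with an estimated correlation. The DNA methylation machinery, which the study's title concerns, moved both ways. Of its 21 genes, 6 rose, 5 fell and 10 did not pass, also adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.712). The dioxygenase TET1 rose by 0.53 ± 0.12 (adjusted p = 0.000891), the deaminase APOBEC3B fell by 1.69 ± 0.24, GADD45A rose by 0.73 ± 0.16 and IDH1 fell by 0.76 ± 0.14. The de novo methyltransferases DNMT3A (-0.30 ± 0.14, adjusted p = 0.107) and DNMT3B (-0.21 ± 0.19, adjusted p = 0.433) did not pass.

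Signalling lists at 72 h showed FGF and ERK targets down in 14 of 17 genes, with EPHA4 among the 2 that rose, both also when adjusted over the list alone (camera adjusted p = 2.9e-08; adjusted p = 0.0741 with an estimated correlation). Of 13 Nodal and Activin targets, 8 fell, 2 rose and 3 did not pass, 9 and 2 adjusted over the list alone (adjusted p = 0.00220; adjusted p = 0.0229 with an estimated correlation). The call ended with genes above background on at least 20 arrays (-0.11, adjusted p = 0.268), and with groups below background held at the background the list's mean went from -0.44 to -0.24 and its median from -0.41 to -0.16. The 2 rises were SHISA2, which retains Wnt and FGF receptors, and BMP7, a BMP ligand, at 1.34 ± 0.22. LEFTY2, a Nodal antagonist, stood at -0.30 ± 0.12 (adjusted p = 0.0581). Of 8 tested BMP targets, 4 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.0397; adjusted p = 0.123 with an estimated correlation). The homeobox gene DLX5 was at least 2.47-fold higher, the ligand BMP2, above background on 2 arrays at 0 h, rose by 1.70 ± 0.17 and the inhibitory SMAD6 by 1.01 ± 0.13, whereas the pseudoreceptor BAMBI fell by 1.77 ± 0.27. ID3, a direct BMP target, stood at -0.20 ± 0.23 (adjusted p = 0.540). Of 11 Wnt targets 4 rose and none fell, also adjusted over the list alone (adjusted p = 0.0298; adjusted p = 0.345 with an estimated correlation). LEF1, above background on 1 array at 0 h, rose by 1.49 ± 0.20 and SP5 was at least 1.99-fold higher. This list call was lost without replicate 4 at 0 h (adjusted p = 0.0511) and without replicate 2 at 72 h (0.0615), and in 4 other alternatives (adjusted p from 0.0596 to 0.199).

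Metabolic and junction lists fell at 72 h under the preset correlation only. Of 23 sterol synthesis genes, 15 fell and 1 rose, 16 and 1 adjusted over the list alone, HMGCS1 by 1.41 ± 0.22, DHCR7 by 1.22 ± 0.15 and FASN, the fatty acid synthase, by 1.05 ± 0.14 (adjusted p = 4.3e-06; adjusted p = 0.204 with an estimated correlation). Glycolysis genes fell in 12 of 20 and rose in none, also adjusted over the list alone, ALDOC by 1.31 ± 0.19 and HK1 by 1.03 ± 0.13, or -0.69 with the mean of its probes (adjusted p = 0.00571; adjusted p = 0.556 with an estimated correlation). Of 19 genes of the amino acid and ER stress response, 10 fell and 2 rose, also adjusted over the list alone, among them ASNS by 1.15 ± 0.20 and the amino acid transporter SLC7A5 by 1.53 ± 0.25 (adjusted p = 0.0119; adjusted p = 0.161 with an estimated correlation). Immediate early genes fell in 5 of 13, MYC by 1.11 ± 0.31 (adjusted p = 0.0105; adjusted p = 0.553 with an estimated correlation). Epithelial junction genes fell in 7 of 22 and rose in none, EPCAM by 1.04 ± 0.23 and CLDN7 by 1.01 ± 0.19 (adjusted p = 0.0119; adjusted p = 0.556 with an estimated correlation). This call ended without replicate 2 at 72 h (adjusted p = 0.0733), with only replicates 3 and 4 (0.130) and without the 6 arrays that deviate alike from the others of their time (0.0563). CDH1, the E-cadherin, stood at -0.06 ± 0.13 (adjusted p = 0.771). These last 2 lists gave the same counts adjusted over the list alone.

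**Figure D3:**
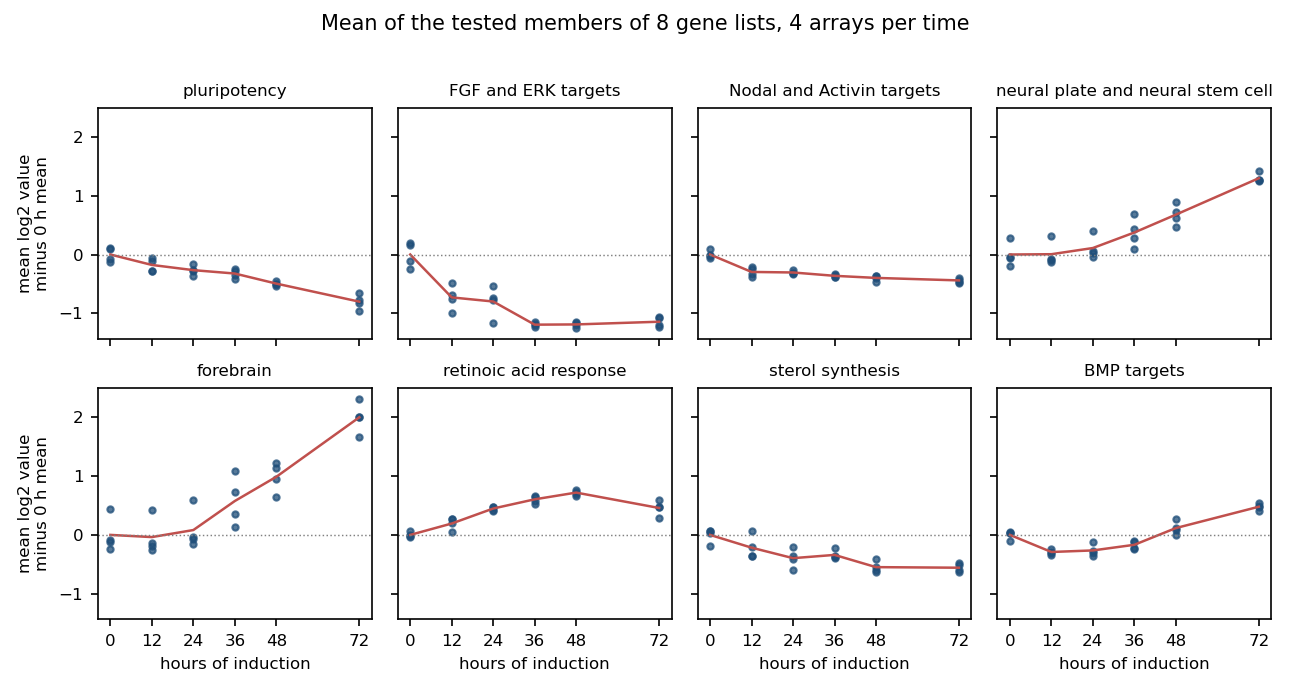
Mean log2 signal of the members of 8 gene lists relative to their mean at 0 h (vertical axis) against time in hours (horizontal axis), with 1 point per array and a line through the means of 4 arrays. The neural plate list reaches 1.29 and the FGF and ERK list -1.14 at 72 h, or 1.22 and -1.06 with groups below background held at the background, which takes the Nodal and Activin list from -0.44 to -0.24. With only genes above background on at least 20 arrays, the FGF and ERK mean was smaller in size.

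The remaining lists did not pass at 72 h. In camera's preset test, adjusted p was 0.0831 for G2 and M phase (9 of 27 genes rose, none fell), 0.963 for S phase (4 rose and 2 fell of 24, or 2 and 2 adjusted over the list alone) and 0.167 for p53 targets (2 rose and 7 fell of 16). It was 0.436 for the hypoxia response (1 rose and 5 fell of 18), 0.316 for the Notch pathway (7 rose and 2 fell of 14) and 0.120 for the retinoic acid response (3 rose and 1 fell of 7). Markers of other cell types that such cultures could hold did not pass as lists either. Adjusted p was 0.963 for endoderm (2 rose and 1 fell of 7), 0.394 for trophoblast and amnion (2 and 1 of 7), 0.680 for epidermal and surface ectoderm (1 and 2 of 7). For the next lists it was 0.297 for fibroblast and smooth muscle (2 and 3 of 13), 0.460 for neural crest (2 and 4 of 10, or 2 and 5 adjusted over the list alone), and 0.175 for mesenchymal genes (6 and 2 of 13). It was 0.206 for midbrain, hindbrain and HOX genes (3 and 1 of 6) and 0.589 for neuronal differentiation (4 and 2 of 13). Except where another count is given, these counts were the same adjusted over the list alone. Only 2 of 24 primitive streak and mesoderm genes were bright enough to test, too few for a list test, and both fell. SOX1, the mesoderm factor TBXT and the endoderm factor SOX17 lay above background on 0 of 24 arrays, ID1 on 2 and LEFTY1 on 1, and these genes were not tested. Mean, median and test differed in sign for the DNA methylation, endoderm and S phase lists.

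All 3665 calls at 72 h came from limma with Benjamini-Hochberg adjustment, 35.9% of the genes tested. At 3174 genes (31.1%) the 4 arrays of 1 time all lay above the 4 of the other, which chance gives for 2.86%. Here and below, this 2.86% is a mean over all splits of the arrays. Its spread over splits was not computed, and arrays that deviate as a whole can carry a single split above it. For 7 called genes different probes disagreed in direction. There were 1070 higher and 1100 lower with only replicates 1 and 2 and 814 and 802 with only replicates 3 and 4, which were tested apart because these sets differ slightly in the lower quartile of their values. The BMP list's call was lost without replicate 2 at 0 h (adjusted p = 0.0670), with only replicates 3 and 4 (0.0527) and in 4 other alternatives (adjusted p from 0.0976 to 0.199).

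The comparison of 12 h with 0 h shows the first response. Transcripts of FGF and ERK feedback were among those that fell. DUSP6 fell by 2.61 ± 0.26 on the log2 scale (6.10-fold; adjusted p = 8.2e-07), SPRY4 by 2.00 ± 0.18 and ETV5 by 1.72 ± 0.31, with DUSP6 and ETV5 still above background on 3 of 4 arrays. ID3, a direct target of BMP signalling, fell by 1.55 ± 0.23 (adjusted p = 0.000205). The list of 8 BMP targets did not pass at 12 h (camera adjusted p = 0.0668, and adjusted p = 0.161 with an estimated correlation). In it 1 gene rose, 2 fell and 5 did not pass, or 1 rose and 3 fell adjusted over the list alone. Of 7 tested metallothioneins, which bind zinc and copper and were grouped after their values were seen, 5 rose, among them MT1E at 2.90 ± 0.53, MT1G at 2.65 ± 0.61 and MT2A at 2.64 ± 0.49. MT1X (1.78, adjusted p = 0.141) and MT1M (1.57, adjusted p = 0.101) did not pass. Their sequences are so alike that the value of a single member is uncertain. Replicate 3 at 12 h rose little, with MT2A at 10.09 and MT1G at 11.22 against 0 h means of 9.59 and 10.67. The other arrays at 12 h lay at 12.43 to 13.75 for MT2A and 13.66 to 14.63 for MT1G. GADD45G, a stress and growth-arrest gene, rose by 2.07 ± 0.29 and ACTA1, an actin of striated muscle, by 2.06 ± 0.16. NANOG was already lower by -0.96 ± 0.16 (adjusted p = 0.000773) and POU5F1 stood at -0.26 ± 0.11 (adjusted p = 0.188).

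Of 17 FGF and ERK targets, 9 fell at 12 h and none rose, 10 adjusted over the list alone (camera adjusted p = 2e-11; adjusted p = 0.0259 with an estimated correlation). Of 16 p53 targets, 7 fell and none rose, 14 adjusted over the list alone, with ZMAT3 at -1.02 ± 0.16 and TNFRSF10B at -0.76 ± 0.12 (adjusted p = 3.2e-10; adjusted p = 0.0246 with an estimated correlation). Of 13 Nodal and Activin targets, 4 fell, 5 adjusted over the list alone (adjusted p = 0.000574; adjusted p = 0.0206 with an estimated correlation). The smooth muscle genes ACTG2 and CNN1 rose by 1.90 ± 0.19 and 1.70 ± 0.17 and TAGLN by 1.38 ± 0.25. Their fibroblast and smooth muscle list held 6 rises and 2 falls among 13, also adjusted over the list alone (adjusted p = 0.0119; adjusted p = 0.161 with an estimated correlation). This call ended without replicate 3 at 0 h (adjusted p = 0.0659) and in the rank-based test (0.1995). Under the preset correlation only, 3 more lists passed. Sterol synthesis was lower in 3 of 23 genes, or 5 with 1 higher adjusted over the list alone (adjusted p = 0.000299, and adjusted p = 0.329 with an estimated correlation). Pluripotency was lower in 3 of 21, or 4 adjusted over the list alone (0.0220, and adjusted p = 0.329 with an estimated correlation). Epithelial junctions were higher in 3 of 22, or 4 adjusted over the list alone (0.0266, and adjusted p = 0.556 with an estimated correlation). The pluripotency call was lost without replicate 2 or 3 at 0 h or replicate 3 at 12 h (adjusted p = 0.0670, 0.156 and 0.0774), as was the junction call (0.0715, 0.0620 and 0.0960). The pluripotency call was also lost in 5 alternatives (adjusted p from 0.0811 to 0.451), and the junction call with array weights (0.0707) and with only replicates 3 and 4 (0.0639). In the neural plate list 2 genes rose and 4 fell of 35, or 4 and 4 adjusted over the list alone (adjusted p = 0.992), SOX21 rising by 1.63 ± 0.21 and NES, the intermediate filament nestin, by 0.87 ± 0.15. Mean, median and test differed in sign for the neural plate, neuronal, Notch and Wnt lists at 12 h.

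EGR1, an immediate early gene that ERK induces, fell by 1.93 ± 0.51 (adjusted p = 0.0229). Its call was lost without replicate 1 or 4 at 0 h or replicate 1, 2 or 4 at 12 h (adjusted p up to 0.118). Leaving out 1 array moved the 282 higher and 339 lower calls to 120 and 170 (without replicate 1 at 0 h), 450 and 554 (replicate 3 at 0 h), or 125 and 161 (replicate 4 at 0 h). They became 170 and 182 (replicate 1 at 12 h) or 147 and 191 (replicate 4 at 12 h), and the 2-fold lower count went from 19 to 29 (replicate 2 at 0 h). Within the sets of replicates, the counts were 65 and 108 in replicates 1 and 2 and 19 and 12 in replicates 3 and 4, and a fit of these 8 arrays alone gave 112 and 139. Another of the 35 splits of the 8 arrays gave 705 genes, against 621 for the real one, and other splits gave up to 11 lists with the preset correlation, against 7. Of all genes 876 (8.57%) had non-overlapping arrays, against a mean of 2.86% over all splits by chance. A single split can exceed that mean, so this share does not set chance aside.

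At 24 h, 5 of the 7 metallothioneins were higher and MT1X (1.04, adjusted p = 0.420) and MT1M (1.32, adjusted p = 0.170) did not pass. The higher ones included MT1E by 2.97 ± 0.53, MT2A by 2.80 ± 0.49, MT1G by 2.52 ± 0.61 and MT1H by 2.42 ± 0.55. CUZD1 had risen by 2.83 ± 0.39 (7.11-fold; adjusted p = 4.4e-05). DUSP6 fell by 2.85 ± 0.26, ETV5, above background on 3 arrays, by 2.18 ± 0.31, ETV4, another ETS factor of the FGF response, by 1.83 ± 0.21 and the surface glycoprotein THY1 by 1.84 ± 0.18 (adjusted p = 5.4e-07). ID3 was lower by -1.59 ± 0.23. The BMP list did not pass at 24 h (camera adjusted p = 0.269, and adjusted p = 0.435 with an estimated correlation). In it 1 of 8 genes was lower and 0 higher, or 2 and 0 adjusted over the list alone. Retinoic acid response genes rose at 3 of 7 with none lower, also adjusted over the list alone (camera adjusted p = 0.00107; adjusted p = 0.0229 with an estimated correlation). CRABP2, a retinoic acid carrier, rose by 1.05 ± 0.13 and the retinaldehyde reductase DHRS3 by 1.25 ± 0.20.

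Of 17 FGF and ERK targets 10 were lower at 24 h, also adjusted over the list alone (adjusted p = 9.9e-12; adjusted p = 0.0246 with an estimated correlation). Of 13 Nodal and Activin targets 4 fell and 1, BMP7, rose, or 6 and 1 adjusted over the list alone (adjusted p = 0.000230; adjusted p = 0.0206 with an estimated correlation). Sterol synthesis genes fell in 12 of 23 and rose in 2, or 14 and 2 adjusted over the list alone, with INSIG1 at -0.87 ± 0.13 (adjusted p = 2.6e-09; adjusted p = 0.107 with an estimated correlation). Pluripotency genes fell in 8 of 21, or 8 with 1 rise adjusted over the list alone (adjusted p = 0.00506; adjusted p = 0.207 with an estimated correlation), POLR3G by 0.99 ± 0.17. The S phase list, 3 of 24 lower or 4 adjusted over the list alone, passed only with the preset correlation (adjusted p = 0.000569; adjusted p = 0.242 with an estimated correlation). So did the epithelial junction list with 1 of 22 higher, also adjusted over the list alone (0.00895; adjusted p = 0.548 with an estimated correlation). The pluripotency call was lost in 4 alternatives (adjusted p from 0.139 to 0.411) and the S phase call with only replicates 1 and 2 (0.103). SOX21 had risen by 2.39 ± 0.21. POU5F1 fell by 0.38 ± 0.11 (adjusted p = 0.0409), a call kept only when replicate 2 at 0 h was the array left out (adjusted p up to 0.113 without another). OTX2 stood at 0.96 ± 0.30 (adjusted p = 0.0516). Mean, median and test differed in sign for the DNA methylation, forebrain and neuronal lists at 24 h. The 406 higher calls became 259 without replicate 3 at 0 h. Within replicates 1 and 2 the counts were 65 higher and 40 lower, within replicates 3 and 4 they were 51 and 52, and a fit of the 8 arrays alone gave 212 and 137. Of all genes 1095 (10.7%) had non-overlapping arrays, against 2.86% by chance.

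At 36 h, SOX21 was higher by 3.08 ± 0.21 on the log2 scale (8.45-fold; adjusted p = 5.2e-10) and IRX3, an Iroquois factor of the neural plate, by 2.66 ± 0.30. PKDCC was higher by 2.46 ± 0.32, CUZD1 by 2.38 ± 0.39 and the growth factor binding protein IGFBP3 by 2.38 ± 0.36. OTX2 rose by 1.40 ± 0.30 (adjusted p = 0.00176), while PAX6 stood at 0.00 ± 0.27 (adjusted p = 0.995). DUSP6 and ETV5 were below background on all 4 arrays, DUSP6 at least 9.91-fold lower. SPRY4 was lower by -2.97 ± 0.18, NTS by -2.49 ± 0.27 and ETV4, above background on 3 arrays, by -2.29 ± 0.21. NANOG fell by 1.32 ± 0.16 and POU5F1 by 0.65 ± 0.11 (adjusted p = 0.000193).

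Of 35 neural plate genes 14 rose and 4 fell at 36 h, or 15 and 5 adjusted over the list alone, HESX1 rising by 1.86 ± 0.32 and the Wnt modulator SFRP2 falling by 1.60 ± 0.31 (adjusted p = 0.000976; adjusted p = 0.526 with an estimated correlation). FGF and ERK targets fell in 13 of 17, or 13 with 1 rise adjusted over the list alone (4.1e-14; adjusted p = 0.0206 with an estimated correlation). Nodal and Activin targets fell in 7 and rose in 2 of 13, or 9 and 2 adjusted over the list alone (0.000746; adjusted p = 0.0206 with an estimated correlation). Retinoic acid response genes rose in 3 of 7, also adjusted over the list alone, MEIS2 being at least 1.80-fold higher (0.00454; adjusted p = 0.0319 with an estimated correlation). Under the preset correlation only, 5 more lists passed. In the p53 list 8 of 16 genes were lower, or 10 with 1 higher adjusted over the list alone (0.000106, and adjusted p = 0.161 with an estimated correlation). In sterol synthesis 8 were lower and 1 higher of 23, or 11 and 1 adjusted over the list alone (1.1e-05, and adjusted p = 0.207 with an estimated correlation). In pluripotency 8 were lower and 2 higher of 21, or 9 and 4 adjusted over the list alone (0.00820, and adjusted p = 0.233 with an estimated correlation). In glycolysis 3 were lower of 20, also adjusted over the list alone (0.0220, and adjusted p = 0.592 with an estimated correlation). In endoderm 1 was higher of 7, or 5 adjusted over the list alone (0.0397, and adjusted p = 0.123 with an estimated correlation). The 1 endoderm gene was CLDN6, a claudin that stem cells also make, at 0.38 ± 0.10. Its call was lost without replicate 1 at 0 h or 2 at 36 h (adjusted p up to 0.0595). The glycolysis call was lost without replicate 3 or 4 at 0 h or 1 or 4 at 36 h (adjusted p up to 0.0764). The endoderm call was lost without replicate 2 or 3 at 0 h or 1 or 3 at 36 h (up to 0.105), with a lower background (0.0717) and with only replicates 3 and 4 (0.0876). The pluripotency call was lost in 3 alternatives (adjusted p from 0.224 to 0.765) and the retinoic acid call in the rank-based test (0.260). With only replicates 1 and 2 the glycolysis (0.485) and neural plate (0.2004) calls were lost.

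CDH1 was higher by 0.53 ± 0.13 at 36 h (adjusted p = 0.00631). SOX2 was higher by 0.51 ± 0.17 (adjusted p = 0.0407). LEFTY2, above background on 3 arrays, was lower by -0.39 ± 0.12 (adjusted p = 0.0285). The SOX2 call was lost after cyclic loess, with no filter on dim genes and without replicate 1, 3 or 4 at 0 h or at 36 h (adjusted p up to 0.170). The LEFTY2 call was lost without replicate 1, 3 or 4 at 0 h or 3 or 4 at 36 h (up to 0.125). With only replicates 1 and 2 LEFTY2 stood at 0.02 on the other side (adjusted p = 0.962). Mean, median and test differed in sign for the Notch and Wnt lists at 36 h. The 813 higher calls fell to 510 without replicate 1 and to 509 without replicate 4 at 0 h. Within replicates 1 and 2 the counts were 333 higher and 491 lower and within replicates 3 and 4 they were 201 and 208. Of all genes 1773 (17.4%) had non-overlapping arrays, against 2.86% by chance.

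At 48 h, PKDCC was higher by 3.57 ± 0.32, SOX21 by 3.40 ± 0.21, IRX3 by 3.20 ± 0.30. SHISA2 was higher by 2.91 ± 0.32 and FRZB by 2.90 ± 0.32. OTX2 rose by 2.03 ± 0.30 (adjusted p = 2e-05) and SOX2 by 0.90 ± 0.17, while PAX6 stood at 0.34 ± 0.27 (adjusted p = 0.415). DUSP6 and ETV5 were below background on all 4 arrays. NTS, above background on 3 arrays, was lower by -3.46 ± 0.27, SPRY4, above background on 2 arrays, by -3.31 ± 0.18 and ADM by -2.95 ± 0.46. NANOG fell by 1.96 ± 0.16, to a level above background on 2 arrays, and POU5F1 by 0.87 ± 0.11. CDH1 was higher by 0.58 ± 0.13 (adjusted p = 0.00217).

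Neural plate genes rose in 18 and fell in 3 of 35 at 48 h, or 20 and 4 adjusted over the list alone (adjusted p = 7.9e-08; adjusted p = 0.207 with an estimated correlation). Forebrain genes rose in 5 and fell in 1 of 10, also adjusted over the list alone, FEZF1 by 2.71 ± 0.36 (adjusted p = 0.00630; adjusted p = 0.390 with an estimated correlation). FGF and ERK targets fell in 13 and rose in 1 of 17, also adjusted over the list alone (2.5e-12; adjusted p = 0.0229 with an estimated correlation). Nodal and Activin targets fell in 9 and rose in 2 of 13, also adjusted over the list alone (0.000226; adjusted p = 0.0206 with an estimated correlation). Retinoic acid response genes rose in 4 of 7, also adjusted over the list alone, CRABP2 by 1.72 ± 0.13 (0.000976; adjusted p = 0.0229 with an estimated correlation). Sterol synthesis fell in 16 and rose in 1 of 23, or 17 and 1 adjusted over the list alone (3.5e-09; adjusted p = 0.107 with an estimated correlation). Pluripotency fell in 9 and rose in 2 of 21, also adjusted over the list alone (0.000261, and adjusted p = 0.107 with an estimated correlation). Glycolysis fell in 7 of 20, or 8 adjusted over the list alone (0.00820, and adjusted p = 0.556 with an estimated correlation). The amino acid and ER stress response fell in 5 and rose in 1 of 19, or 8 and 1 adjusted over the list alone (0.0246, and adjusted p = 0.207 with an estimated correlation). Immediate early genes fell in 3 of 13, also adjusted over the list alone (0.0350; adjusted p = 0.560 with an estimated correlation). The immediate early call was lost without replicate 1 or 4 at 0 h or at 48 h (adjusted p up to 0.167), with genes above background on at least 20 arrays (0.117) and with only replicates 1 and 2 (0.224). Also lost were the pluripotency call with that filter (0.268), the forebrain and retinoic acid calls in the rank-based test (0.0698 and 0.0748) and the forebrain and glycolysis calls with only replicates 1 and 2 (0.0867 and 0.139). Mean, median and test differed in sign for the neuronal list at 48 h. Within replicates 1 and 2 the counts were 334 higher and 344 lower, and within replicates 3 and 4 they were 533 and 489. Of all genes 2125 (20.8%) had non-overlapping arrays, against 2.86% by chance.

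From 12 to 24 h, SMOC2, a matricellular protein, rose by 1.16 ± 0.30 (adjusted p = 0.0246), the potassium channel gene KCNK12 by 1.13 ± 0.21 and the netrin receptor gene UNC5A by 1.08 ± 0.24. DTNA, coding for dystrobrevin, fell by 1.36 ± 0.27, the splicing coactivator RBM14 by 1.24 ± 0.20 and the natriuretic peptide gene NPPB by 1.18 ± 0.19 (adjusted p = 0.00259). In all 339 genes rose and 332 fell, 6 and 7 of them by at least 2-fold. Non-overlapping arrays were seen at 1131 genes (11.1%), against a mean of 2.86% over all splits by chance, which a single split can exceed. The SMOC2 call was lost without replicate 1 or 2 at 12 h or 4 at 24 h (adjusted p up to 0.100). Another of the 35 splits of the 8 arrays gave 866 genes, against 671 for the real one. The counts depended on single arrays. They were 167 and 149 without replicate 1, 91 and 77 (3 lower by 2-fold) without replicate 2, 537 and 533 (15 and 13 by 2-fold) without replicate 3 and 164 and 141 without replicate 4 at 12 h. They were 144 and 148 without replicate 1, 538 lower (15 higher by 2-fold) without replicate 2, 212 and 177 without replicate 3 and 125 and 101 without replicate 4 at 24 h. Replicates 1 and 2 alone gave 71 and 43, and replicates 3 and 4 gave 0 and 0 in limma, with 1455 genes at an unadjusted p under 0.05.

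From 24 to 36 h, 705 genes rose and 762 fell, 20 and 37 of them by at least 2-fold. HESX1 rose by 2.02 ± 0.32 (4.05-fold; adjusted p = 0.000707), ANK2, an ankyrin, by 1.34 ± 0.21 from a level above background on 3 arrays and RBM14 by 1.29 ± 0.20. MT1G fell by 2.53 ± 0.61, TXNIP, which binds thioredoxin, stood at -2.32 ± 0.49 and MT1E at -2.27 ± 0.53. Non-overlapping arrays were seen at 1814 genes (17.8%), against 2.86% by chance. The counts were 376 and 470 without replicate 3 and 219 and 291 (10 and 23 by 2-fold) without replicate 4 at 24 h, 316 and 372 without replicate 1 at 36 h, and 35 and 72 by 2-fold without replicate 2 at 24 h. Replicates 1 and 2 alone gave 5 and 20, and replicates 3 and 4 gave 135 and 129.

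From 36 to 48 h, LMO1 rose by 2.23 ± 0.29 (adjusted p = 0.000290) from a level above background on 2 arrays, SHISA2 by 1.74 ± 0.32 and TXNIP by 1.75 ± 0.49 (adjusted p = 0.0374). CSRP1, a LIM protein of smooth muscle, fell by 1.77 ± 0.30, DTNA by 1.71 ± 0.27 and PRICKLE1, a planar cell polarity gene, by 1.64 ± 0.27. In all 296 genes rose and 242 fell, 16 and 11 by at least 2-fold, with 1565 (15.3%) non-overlapping, against 2.86% by chance. The TXNIP call was kept only when replicate 4 at 36 h was the array left out (adjusted p up to 0.109 without another). The counts were 150 and 118 without replicate 1, 95 and 72 (8 higher by 2-fold) without replicate 2 and 92 and 72 (9 and 6 by 2-fold) without replicate 3 at 36 h, with 21 lower by 2-fold without replicate 4. At 48 h they were 99 and 80 (9 and 6 by 2-fold) without replicate 1, 155 lower without replicate 2, 131 and 105 without replicate 3 and 6 lower by 2-fold without replicate 4. Replicates 1 and 2 alone gave 12 and 11, and replicates 3 and 4 gave 0 and 0 in limma, with 889 genes at an unadjusted p under 0.05.

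From 48 to 72 h, PAX6 rose by 2.79 ± 0.27 (6.91-fold; adjusted p = 3e-07) from a level above background on 2 arrays, DLK1 by 2.41 ± 0.36 from a level above background on 3 arrays and MAPK10, the neural JNK3, by 2.07 ± 0.19. CUZD1 fell by 1.97 ± 0.39, DHRS3 by 1.66 ± 0.20 and CFAP95 by 1.63 ± 0.35. In all 275 genes rose and 359 fell, 40 and 50 by at least 2-fold, with 1208 (11.8%) non-overlapping, against 2.86% by chance. The counts were 140 and 206 without replicate 2 and 171 and 219 without replicate 3 at 48 h, and 149 and 222 without replicate 1 and 164 and 199 (29 lower by 2-fold) without replicate 2 at 72 h. Replicates 1 and 2 alone gave 208 and 313, and replicates 3 and 4 gave 15 and 7.

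A gene was counted as transient when it changed by at least 2-fold from 0 h and by 72 h had moved back at least 2-fold. There were 42 such peaks, 17 with their largest change at 12 h, 10 at 24 h, 10 at 36 h and 5 at 48 h, and 7 troughs, 2 at 24 h and 5 at 36 h. Among the largest peaks, MT1E reached 7.82-fold and MT2A 6.95-fold at 24 h and MT1G 6.28-fold at 12 h, and CUZD1 reached 7.11-fold at 24 h. Other peaks were those of ACTA1, 4.16-fold, ACTC1 3.76-fold, ACTG2 3.74-fold, CNN1 3.24-fold and TAGLN 2.60-fold higher at 12 h. Moving back did not always mean a return to the 0 h level. At 72 h against 0 h, MT1G stood at -2.40 (limma adjusted p = 0.00295) and MT2A at -1.40 (0.0282). RHBDL3, a peak chosen after its values were seen, was still higher by 1.30 (0.000523). MT1E (-1.30, 0.0555) and CUZD1 (0.49, 0.351) did not pass. The deepest troughs were those of the calcium sensor gene VSNL1, lower by -1.83 ± 0.27 at 36 h, SFRP2 (-1.60 ± 0.31 at 36 h), ID3 (-1.59 ± 0.23 at 24 h) and PDGFRB, a growth factor receptor above background on 2 arrays at 36 h (-1.30 ± 0.19). The number of troughs was 11 without replicate 2 or 3 at 0 h or replicate 4 at 36 h, and within replicates 1 and 2 and within replicates 3 and 4 there were 16 and 4. The latter set gave 21 peaks.

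**Figure D4:**
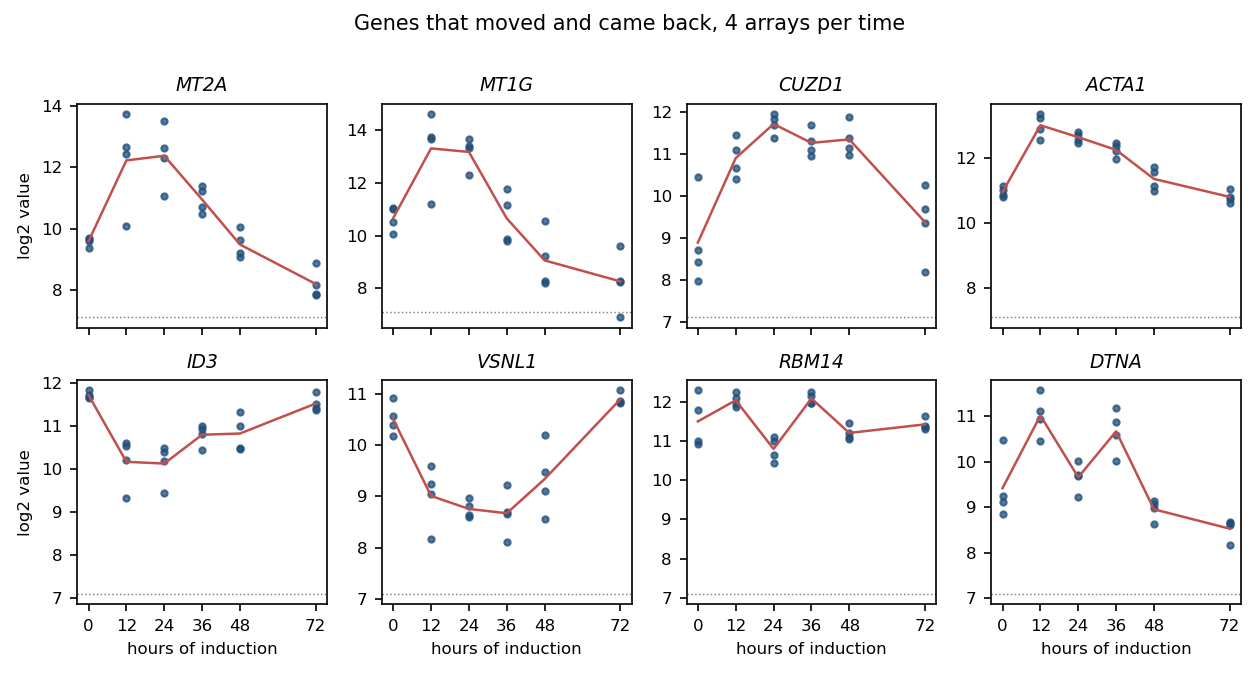
Log2 signal (vertical axis) of 8 genes against time in hours (horizontal axis), with 1 point per array and a red line through the means of 4 arrays. MT2A and MT1G peak at 12 and 24 h and end below their 0 h means at 72 h, and ACTA1 peaks at 12 h. ID3 and VSNL1 dip and return, and RBM14 and DTNA are high at 12 and 36 h. RBM14 and DTNA were added to this plot after their values were seen.

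Each gene at least 2-fold changed at 72 h was placed at the time from which it stayed changed. Of these 419 genes, 13 had changed by 12 h (3 higher and 10 lower), 13 from 24 h (9 and 4), 68 from 36 h (30 and 38), 90 from 48 h (53 and 37) and 235 at 72 h alone (106 and 129). DUSP6, SPRY4 and ETV5 were among those lower from 12 h and SOX21 among those higher from 12 h. The number from 24 h was 21 without replicate 2 at 0 h. Of the 32 genes at least 2-fold higher at 12 h, 4 were so at 72 h, against 0.63 for independent lists, and of the 19 lower, 12 against 0.41, while 5 genes were changed in opposite directions. The 2 comparisons share the 0 h arrays: simulated unchanged groups gave 0 shared genes but made no 2-fold call at 12 or 72 h, so they say nothing on sharing, and with the 0 h arrays split between the comparisons the counts were 4 or 4 higher and 14 or 9 lower. Without replicate 2 at 0 h, 7 higher genes were shared, and within replicates 1 and 2 and replicates 3 and 4 the lower ones numbered 7 and 5.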

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

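The tests of the 6 arrays below against the sets of replicates and against the whole course were chosen after the result was seen. A group of 4 arrays was singled out when the gap between its highest or lowest array and the nearest other exceeded the 95% critical value of Dixon's test as a share of the range. This held for 18 of 371 groups, 9 of 209 for genes and 9 of 162 for lists, where chance gives about 1 in 20, or 18.6.

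Among single genes, TNFRSF19 at 72 h was high in replicate 2 (11.98 against a mean of 11.28 in the others, gap 0.889 of the range) and POU5F1 at 36 h was high in replicate 2 (11.88 against 11.64, gap 0.831). TET1 at 12 h was high in replicate 3 (9.35 against 8.83, gap 0.923) and DNMT3B at 72 h was high in replicate 4 (10.52 against 9.90, gap 0.879). SHISA2 at 0 h was high in replicate 4 (10.78 against 9.80, gap 0.926) and FST at 0 h was high in replicate 2 (9.77 against 8.26, gap 0.914). MT1H at 0 h was high in replicate 3 (10.35, gap 0.848), MT1X at 0 h was low in replicate 2 (10.79 against 11.93, gap 0.915), and TXNIP at 36 h was low in replicate 3 (9.98 against 10.54, gap 0.886). List means stood apart for neural plate genes, high at 12 h in replicate 4 (8.90 against 8.49, gap 0.884) and at 72 h in replicate 1 (9.99 against 9.84, gap 0.936). Forebrain genes were high at 24 h in replicate 2 (7.84 against 7.17, gap 0.841), Nodal and Activin targets at 24 h in replicate 4 (8.31 against 8.26, gap 0.839) and p53 targets at 12 h in replicate 3 (8.91 against 8.81, gap 0.873). BMP targets were low at 0 h in replicate 2 (8.41 against 8.56, gap 0.912) and sterol synthesis genes at 0 h in replicate 1 (9.90 against 10.14, gap 0.877). Epidermal genes were low at 48 h in replicate 4 (8.41 against 8.67, gap 0.873) and neural crest genes at 36 h in replicate 3 (7.94 against 7.97, gap 0.874).

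In 6 arrays, 1 per time, the same genes deviated from the other arrays of their time, and 7 of the 18 groups above had 1 of these 6 as the extreme array: replicate 2 at 0, 24 and 72 h and replicate 4 at 12, 36 and 48 h, and the deviation made up 27.0% of the variation within times, the next component 13.7%. CLEC2A, a lectin gene, lay at 7.17 to 7.56 in them and at 9.10 to 10.71 in the others, and ZNF562, a zinc finger gene, at 8.40 to 8.84 against 6.43 to 6.98, both chosen after their values were seen. The sets of replicates are argued against as the source, since 3 of the 6 lay in replicates 1 and 2. A harvest earlier or later along the course cannot be told apart. From 0 to 72 h the deviations correlated across genes at r of -0.14, 0.03, 0.34, 0.36, 0.27 and -0.12 (3 over 0.2) with steps that at 0 and 72 h do not adjoin that time. With the longest change that leaves out their own time, r was 0.121, 0.158, 0.255, 0.400, 0.357 and 0.0467. OTX2 was highest of its time in 6 of the 6, ADM lowest in 5, the neural plate list above its time mean in 5 and the hypoxia list below it in 6. These tallies are not independent evidence on the stage. The 6 arrays were picked by the main component of the deviations over all genes, its sign set so that ADM was low. A separate culture series is untested and stays open, because the labels name none, and no biological explanation other than the stage of the course was tested.

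Measurements without a gene name lay outside the comparisons. At 72 h against 0 h, limma called 255 higher and 282 lower of 2322 tested, and 50 changed by at least 2-fold, 18 higher and 32 lower. The largest were ILMN_1905072 at 3.31 ± 0.25 and ILMN_1805177 at 2.61 ± 0.16, and ILMN_1842237 at -2.42 ± 0.58 and ILMN_1691156 at -2.26 ± 0.47 (SE).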

How the results depend on the processing

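The alternatives with only replicates 1 and 2, only replicates 3 and 4, the column set as a block, the background at the 95th percentile, no repeated values and 6 arrays left out were chosen after seeing the data. The others were planned. Centring and loess were planned after another background correction and were applied here to the deposited log2 values. No named gene or list past the threshold changed direction in these alternatives, apart from LEFTY2 at 36 h, which stood at 0.016 (adjusted p = 0.962) with only replicates 1 and 2. Among 471 comparisons of named genes, 470 kept their side of the threshold after median centring and 465 after cyclic loess, but only 423 with the arrays of the 2 times alone, 431 without the 6 arrays, 441 with no filter on dim genes, 300 with only replicates 1 and 2 (1 reversed) and 266 with only replicates 3 and 4. The counts of genes at 72 h against 0 h ranged from 1627 to 1858 higher and from 1558 to 1711 lower when 1 array was left out. They were 1896 and 1779 after median centring, 1821 and 1873 after cyclic loess, and 1924 and 1843 with no filter on dim genes. The neural plate list kept a mean change of 1.23 to 1.39 and the pluripotency list of -0.85 to -0.75 when 1 array was left out. With no filter on dim genes, which adds dim members, these means at 72 h were 0.99 and -0.73, against 1.29 and -0.80.

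List calls depended on the test. With the estimated correlation, the lists past the threshold numbered 3 at 12 h, 3 at 24 h, 3 at 36 h, 3 at 48 h and 2 at 72 h, against 7, 7, 9, 10 and 12 with the preset one. The neural plate list at 72 h was then not past the threshold (1.29, adjusted p = 0.107), nor was the BMP list (0.48, adjusted p = 0.123). The estimated correlation was 0.274 for the neural plate list and -0.0339 for the BMP list, against 0.01 preset. A larger correlation between genes thus goes with the lost neural plate call but not with the lost BMP call. No further cause was tested. The BMP list also failed in the rank-based test (0.48, adjusted p = 0.167), with genes above background on at least 20 arrays (0.29, 0.199), with only replicates 3 and 4 (0.44, 0.0527), without repeated values (0.44, 0.0976) and without the 6 arrays that stand apart (0.47, 0.0984). With no filter on dim genes, which adds dim members, the list means at 72 h were 0.24 for BMP (adjusted p = 0.0284), -0.27 for Nodal and Activin, 0.46 for Wnt and 1.30 for forebrain genes, against 0.48, -0.44, 0.73 and 2.00. With genes above background on at least 20 arrays the FGF and ERK list stood at -0.46 against -1.14 at 72 h, and the Nodal and Activin list at 72 h (-0.11, adjusted p = 0.268) and the pluripotency list at 12, 24, 36 and 48 h (adjusted p from 0.268 to 0.765) did not pass. POU5F1 at 72 h stood at -1.12 with the mean of its probes, against -1.81. The filter to at least 20 arrays, which tests fewer genes and drops those that start or end dim, gave 12 genes lower by 2-fold at 12 h, 16 higher by 2-fold from 48 to 72 h, 5 shared lower genes, 8 genes first changed at 12 h and 6 lists at 48 h.

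Array weights raised the counts of the intervals, to 612 higher and 598 lower from 12 to 24 h (12 higher by 2-fold), 1103 higher from 24 to 36 h, 727 and 675 from 36 to 48 h and 439 higher from 48 to 72 h, with 14 troughs. The cause was not tested. With a variance trend and robust estimation, 10 genes were higher by 2-fold from 36 to 48 h. A fit of only the arrays of the 2 times compared, with fewer residual degrees of freedom, gave 112 higher and 139 lower at 12 h, 212 and 137 at 24 h, 177 and 138 from 12 to 24 h and 391 lower from 36 to 48 h. Without the 6 arrays that stand apart, the 2-fold counts were 19 higher from 12 to 24 h, 35 higher and 63 lower from 24 to 36 h and 17 lower from 36 to 48 h, with 13 troughs.

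With only replicates 1 and 2, and so with fewer arrays, limma gave 65 higher and 108 lower genes at 12 h, 65 and 40 at 24 h (33 higher by 2-fold), 333 and 491 at 36 h, 334 and 344 at 48 h and 1070 and 1100 at 72 h. The intervals held 71 and 43 from 12 to 24 h (17 and 16 by 2-fold), 5 and 20 from 24 to 36 h (3 and 6) and 12 and 11 from 36 to 48 h (5 and 6), and 76 and 111 by 2-fold from 48 to 72 h. There were 2474 genes varying with time, 16 troughs, 7 shared lower genes, and 5, 54 and 353 genes first changed at 12, 48 and 72 h. With only replicates 3 and 4 the counts were 19 and 12 at 12 h (16 and 5 by 2-fold), 51 and 52 at 24 h (27 higher by 2-fold), 201 and 208 at 36 h (56 lower by 2-fold), 533 and 489 at 48 h and 814 and 802 at 72 h. From 12 to 24 h and from 36 to 48 h limma called 0 genes in either direction, 0 by 2-fold, with 1455 and 889 genes at an unadjusted p under 0.05. From 24 to 36 h they were 135 and 129 (42 higher by 2-fold), and from 48 to 72 h 15 and 7 (10 and 5). There were 1565 genes varying with time, 21 peaks, 4 troughs, 7 and 5 genes shared higher and lower, and 8 and 8 genes first changed at 12 and 24 h.

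With a limit of 1.5-fold there were 139 peaks and 69 troughs, and 48, 72, 206, 276 and 699 genes first changed at 12, 24, 36, 48 and 72 h. With no fold limit 77 higher and 184 lower genes were shared by 12 h and 72 h, against 52.2 and 58.9 for independent lists. These larger counts follow from the lower limits. Both comparisons share the 0 h arrays, so the number for independent lists is not the number for unchanged genes. The split of the 0 h arrays was not run without a fold limit.

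Leaving out 1 array at a time moved the interval and early counts most. At 12 h they ranged from 120 (without replicate 1 at 0 h) to 450 (without replicate 3 at 0 h) higher and from 161 (without replicate 4 at 0 h) to 554 (without replicate 3 at 0 h) lower. Genes lower by 2-fold numbered 13 without replicate 1 at 12 h and 29 without replicate 2 at 0 h. Higher genes at 24 h ranged from 259 (without replicate 3 at 0 h) to 404 (without replicate 2 at 24 h), and at 36 h from 509 (without replicate 4 at 0 h) to 983 (without replicate 3 at 0 h). From 12 to 24 h the range was 91 to 537 higher (without replicate 2 and without replicate 3 at 12 h) and 77 to 538 lower (without replicate 2 at 12 h and at 24 h), with 5 to 15 and 3 to 13 by 2-fold. From 24 to 36 h it was 219 to 1039 higher and 291 to 1005 lower, with 10 to 35 and 23 to 72 by 2-fold, the lowest without replicate 4 and the highest without replicate 2 at 24 h. From 36 to 48 h it was 92 to 305 higher and 72 to 259 lower, with 8 to 24 and 6 to 21 by 2-fold, each highest without replicate 4 at 36 h. From 48 to 72 h it was 140 to 312 higher and 199 to 429 lower, with 29 to 63 lower by 2-fold, each highest without replicate 4 at 48 h. Troughs ranged from 6 to 11, shared higher genes from 4 to 7, genes first changed at 24 h from 11 to 21, lists at 12 h from 4 to 9, and the BMP list from 0.44 (without replicate 2 at 0 h, adjusted p = 0.0670) to 0.50. Of 3768 comparisons of named genes without 1 array, 399 lost their call and 10 gained one. Of 1056 list tests, 22 lost and 31 gained one.

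The replicate numbers did not meet the criterion for pairs, except for replicate 1. Deviations from the group means correlated at r over 0.1 in all 15 pairs of replicate 1, but in 4, 5 and 5 of 15 pairs for replicates 2, 3 and 4, and 8 of 24 arrays correlated best with arrays of their own number. With the replicate block the counts were 352 higher and 409 lower at 12 h and 2042 and 1939 at 72 h, and 5507 genes varied with time. Under this block 132 of 132 list tests and 465 of 471 named gene comparisons kept their side of the threshold. The 6 arrays that deviate alike carry the numbers 2 and 4, so this block does not test a pairing that crosses the numbers. Such a pairing was not fitted and stays open. Alternatives that needed the scanner intensities, namely no background correction and a larger offset, were not run, and neither was the slide as a block, because those columns could not be matched to samples and no slide is given. Signal over background limits the changes of dim genes, since 7543 of 17760 named genes were not tested.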

Other observations

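The tests of a shared metallothionein transcript, of zinc, of growth state, of residuals shuffled around a course without alternation, of 1 set of replicates alone and of the neural and hypoxia lists were chosen after the result was seen. Within gene lists that did not pass as a whole at 72 h, single genes moved in both directions. Of all genes tested, 35.9% passed at 72 h. In the Notch pathway, which times the exit of neural progenitors, HES6, a HES relative of differentiating progenitors, fell by 0.86 ± 0.12 at 12 h and by 1.08 ± 0.12 at 72 h on the log2 scale (SE, n = 4 arrays per time). The ligand DLL1 rose by 1.39 ± 0.25 at 24 h and 1.03 ± 0.25 at 72 h, the modifier LFNG by 0.82 ± 0.19 at 72 h (0.50 with the mean of its probes) and the receptor NOTCH3 by 0.72 ± 0.13 at 36 h. HEY2, a Notch target, fell by 1.23 ± 0.24 at 48 h and was at least 3.69-fold lower at 72 h. Among neuronal genes MAP2, a microtubule protein of dendrites, rose by 1.08 ± 0.14 and DPYSL3, a growth cone protein, by 0.96 ± 0.13 at 72 h, while the neurofilament gene NEFM fell by 0.88 ± 0.12.

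IRX3, an Iroquois factor, rose by 1.37 ± 0.30 at 24 h and 2.60 ± 0.30 at 72 h, with IRX5 at least 2.38-fold higher and the caudal factor CDX4 at least 1.86-fold lower at 72 h. THY1, a surface marker of stem cells and mesenchyme, fell by 1.95 ± 0.18 at 72 h, whereas the cadherin CDH11 rose by 1.88 ± 0.17 and the repressor ZEB2 was at least 3.72-fold higher. SOX9 rose by 1.26 ± 0.19 at 36 h. Of the retinoic acid response, MEIS2 was at least 3.54-fold higher at 72 h and CRABP2 higher by 1.04 ± 0.13, while EGLN3, an oxygen sensor, rose by 1.45 ± 0.10 although ADM of the same hypoxia list fell.

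Some genes were noticed to alternate, with 1672 of 10217 past the threshold in limma for a contrast of the mean of 12 and 36 h with 24 h (weight -0.75) and 0 and 48 h (-0.125 each), 831 above 0 and 841 below, led by RBM14 at 1.13 ± 0.15 and RFTN2, chosen after its values were seen, at -0.65 ± 0.08, and 55 were higher and 55 lower at 12 and 36 h past the threshold in each interval from 12 to 48 h. With the residuals of whole arrays shuffled around a course without alternation, 1 of 100 draws, the real one, gave as many genes (highest other 997) and as many in each interval (110, highest other 65). This argues against chance deviations for this contrast. The shuffles do not allow for its choice after the pattern was noticed in the same arrays. Without the 6 arrays 1831 genes passed, and at least 718 without any 1 array (replicate 4 at 24 h), so no single array held all the calls. These 718 lie under the 997 that a shuffle of all arrays reached, and no shuffles were run without 1 array. A large part played by 1 array therefore stays open. Replicates 1 and 2 as the only source cannot be told apart, since limma called 358 genes within them and 0 within replicates 3 and 4 (2029 and 2219 at an unadjusted p under 0.05), 347 of the 358 had the same sign in replicates 3 and 4 but so had as many in 8 of 100 draws with the residuals of these shuffled (highest other 353), and the set as a block (1873 genes) could not lower the count in this balanced design. A candidate explanation is the body clock with harvests at alternating times of day. Of 14 tested clock genes 6 passed, all with a negative contrast (one-sided Fisher's exact p = 0.0174 across genes, which are not independent). The means of PER2 (-0.47), PER3 (-0.41) and TEF (-0.70) were lower at 12 and 36 h than at 0, 24 and 48 h. The contrast gives 0 h little weight, and single arrays of PER3 and TEF at 0 h overlapped with those at 12 and 36 h. The means of CRY2 (-0.40), NR1D2 (-0.25) and DBP (-0.39) were lower at both than at 24 and 48 h but not both times lower than at 0 h. The core genes BMAL1 (0.05), NR1D1 (-0.02), CLOCK (0.06) and CRY1 (-0.12) did not pass (adjusted p from 0.423 to 0.883). For RBM14, which led the contrast, replicate 3 at 0 h was the highest of the 24 arrays (12.29). Growth state after the daily change of medium cannot be told apart from the body clock. In camera the S phase list passed with the preset correlation (adjusted p = 0.00110, 7 of 24 genes higher and 1 lower) but not with an estimated one (adjusted p = 0.432). The hours of harvest and medium change and the days of hybridisation are not given in the sources used here.

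For the same contrast, 4 other lists passed with the preset correlation and not with an estimated one. Of 16 p53 targets 9 were lower and 1 higher (adjusted p = 3.1e-05; adjusted p = 0.256 with an estimated correlation) and of 13 immediate early genes 5 were lower (0.00154; adjusted p = 0.687 with an estimated correlation). Of 14 Notch pathway genes 4 were lower (0.0285; adjusted p = 0.256 with an estimated correlation), and of 17 FGF and ERK targets 2 (0.0391; adjusted p = 0.809 with an estimated correlation).

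Of 7 metallothioneins, MT1E, MT1G, MT1H, MT2A and MT1F rose at 12 and 24 h, while MT1X (1.78 and 1.04, adjusted p = 0.141 and 0.420) and MT1M (1.57 and 1.32, adjusted p = 0.101 and 0.170) did not pass, MT1F and MT1M being chosen after their values were seen. MT2A at 24 h was higher by 3.44 in replicates 1 and 2 and by 2.16 in replicates 3 and 4, which argues against 1 set as the source for this gene and time. Probes that read 1 shared transcript cannot be told apart from separate genes, since the difference of MT2A and MT1X within arrays moved by 2.45, from -2.06 ± 0.65 (SD, n = 4) at 0 h to 0.40 ± 1.90 at 36 h, with an exact two-sided permutation p of 0.0857. Zinc or another metal in the new medium also stays open, since SLC30A1, a zinc exporter gene chosen after the metallothioneins were seen, stood at -0.11 ± 0.14 at 12 h and 0.21 ± 0.14 at 24 h, with an upper 95% limit of 0.505 that leaves a small rise possible. No untreated cells were sampled at those times, so the compound as a cause was not tested.

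Neural plate and hypoxia list means deviated from their time means in opposite directions across the 24 arrays (Pearson r = -0.73, permutation p = 0.000190 within times, adjusted p = 0.000950 over 5 sets of arrays; Spearman rho = -0.69, p = 0.000780, adjusted p = 0.00390). Without the 2 arrays farthest in the hypoxia list r was -0.72. It was -0.76 within replicates 1 and 2 (permutation p = 0.184) and -0.81 within replicates 3 and 4 (permutation p = 0.124), with 12 arrays each. Over the 18 arrays that do not stand apart r was -0.44 (permutation p = 0.0343, adjusted p = 0.0572; rho = -0.46, p = 0.0781), so the relation rests in part on the 6 arrays.

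Other splits of the arrays were refitted with limma for each comparison. For 12 h against 0 h chance is not excluded, since 2 of 35 splits gave as many genes, the real one with 621 and another with 705, which grouped replicate 3 at 0 h with replicates 1, 2 and 4 at 12 h. Nor is it for 24 h against 12 h, with 2 of 35, the real one with 671 and another with 866, which grouped replicate 3 at 12 h with replicates 1, 3 and 4 at 24 h. The real split alone, 1 of 35, gave as many genes for 24 h against 0 h (737 genes, highest other 128), 36 h (1738, 142), 48 h (2168, 4) and 72 h (3665, 3). So it did from 24 to 36 h (1467, 280), 36 to 48 h (538, 32) and 48 to 72 h (634, 255). This argues against chance in these comparisons. A share of 1 of 35 is the smallest the test can give, and the split tests were not adjusted for their number. Among 100 regroupings of the 24 arrays, 1, the real one, gave as many genes varying with time (4994, highest other 205), which argues against chance. It also alone gave as many transient genes (49, highest other 1), genes shared by 12 h and 72 h (16, 0) and genes placed by first time (419, 0), but 94 of the 99 others made no 2-fold call at any time, so these counts say nothing on return, sharing or timing. Nor do the regroupings tell of the alternation (1672, highest other 410), since they lose every change with time. For lists with the preset correlation chance is not excluded at 12 h (12 of 35 splits, 7 lists, highest other 11), 24 h (12 of 35, 7, highest other 9), 36 h (5 of 35, 9, highest other 10) and 48 h (2 of 35, 10, highest other 10). At 72 h the real split alone gave as many lists (1 of 35, 12, highest other 11). That narrow margin does not exclude chance either, since this test made calls in 20 of 20 simulations without changes. With the estimated correlation the real split alone gave as many lists at 12 h (3, highest other 1), 24 h (3, 0), 36 h (3, 0), 48 h (3, 0) and 72 h (2, 0), which argues against chance.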
